A study of Homo sapiens with 24 samples.

How the data were processed

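The values are the processed array intensities that the authors deposited as a series matrix, 1 intensity per probe set and array, and they were used as deposited. How raw scans were turned into these intensities, and how arrays were scaled, is not given in the sources used here. All 24 arrays of the Affymetrix HG-U133 Plus 2.0 platform were used. Their 54675 probe sets held 0 missing values and 0 identical columns. Values equal to 1 numbered 605 to 698 per LNCaP array and 6 to 13 per VCaP array, the lowest value was 0.5 in LNCaP and 0.05 in VCaP, and the median intensity was 42.7 to 44.8 in LNCaP and 47.6 to 53.2 in VCaP, so the lines were probably processed apart. Every direct comparison was therefore made inside one line, and only changes were set against each other between lines.

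The design text names 3 biological replicates (A, B, C) in each of 8 groups, and the p-values reflect the spread between these samples. The labels name the LNCaP control both as shControl and as siControl, and it is called shControl here because ETV1 was lowered with a short hairpin. Batches, dates and sequences of the RNA interference reagents are not given in the sources used here.

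Each value was turned into log2 of the intensity plus 16. Of the 54675 probe sets, 42898 had a gene in the probe table, 1801 of which named several genes, and 41091 were used for 19775 genes. The gene table paired the genes with their symbols, and 0 symbols had to be changed. Each gene was represented by its probe set with the highest mean over all 24 arrays. A gene was tested in a line when it lay above the array median in at least 3 of the 12 arrays of that line, which kept 12840 genes in VCaP, 12823 in LNCaP and 12305 in both. The probe set that represents ERG lay below this limit in LNCaP.

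Changes were estimated with limma, a linear model with moderated variances, in one fit per line with 4 groups of 3 arrays and a common spread. The comparisons were knockdown against control with EtOH, knockdown against control with DHT, DHT against EtOH in control cells, DHT against EtOH in knockdown cells, and the interaction, which is the DHT response of knockdown cells minus that of control cells. A fit of all 24 arrays gave the differences between lines, always LNCaP minus VCaP. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was said to rise, fall or change when its adjusted p was below 0.05. Changes are log2 units with their standard error from limma, and n = 3 arrays per group throughout. All tests are two-sided. Exact permutation p-values for the RNA quality ratios cannot fall below 0.1 with 3 against 3 arrays.

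Gene lists were written from general knowledge. The 15 lists are androgen induced, androgen repressed, androgen metabolism, cholesterol synthesis, fatty acid synthesis, cell cycle, unfolded protein response, interferon response, p53 targets, invasion mesenchymal, ETS family, luminal epithelium, basal epithelium, neuroendocrine and non epithelial (markers of fibroblasts, endothelium and leukocytes). Each was tested with camera, which compares its members with all other genes, with a preset correlation of 0.01 between genes and adjustment over the 15 lists of a comparison. Of 195 list tests 62 passed, and 20 of these held when camera estimated the correlation from the data. For every passed list the median, the mean and the test had the same sign. A further 8 tests asked whether genes that rose or fell by at least 1 log2 unit with DHT in control cells of one line shifted after knockdown in the other line, with adjustment over the 8 tests and no shared arrays. Correlations between 2 sets of changes run across genes, which are not independent, so they carry no p-value, and their error is a jackknife over left-out arrays.

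Genes named in the text follow a fixed rule. For each comparison of 2 groups these are the 10 highest and 10 lowest changes past the threshold whose arrays did not overlap between groups, an event with a chance share of 10% for 3 against 3 arrays. For each interaction and line difference they are the 5 highest and 5 lowest. For each list they are up to 2 risen and 2 fallen members with the smallest adjusted p. ERG, ETV1, TMPRSS2 and KLK3 are always reported. The text names part of the genes so chosen, the tables hold all of them, and a gene so chosen in one comparison is at times given in another. Probe sets of the UGT2B and AKR1C families and those ending in _x_at may bind related transcripts and are marked where named.

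The comparisons, lists, thresholds and alternatives were chosen before the data were examined, with the exceptions named below. The alternatives were the average of all probe sets of a gene, exclusion of _x_at and _s_at probe sets, no intensity filter, a filter at the 60th percentile, quantile normalization, centring of arrays on their median, a trended and robust variance, array weights, a change of at least 1 log2 unit, an adjusted p below 0.01, a fit of only the groups compared, a fit of all 24 arrays, replicate letters as blocks, pseudocounts of 1 and 32, Spearman correlation, and each array left out in turn. Fits with the ACTB or the GAPDH 3' to 5' ratio as a covariate were chosen after seeing the data. Scaling moved the median change of all genes by less than 0.1 in every comparison.

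Each fit was tried on simulated arrays with the gene means and spreads of the data and with changes of known size. A change of 0.5 log2 units was found for 79.1% of altered genes in the siERG comparison with EtOH, 52.2% in the VCaP interaction and 58.2% in the LNCaP interaction, and a change of 1 log2 unit for 91.0%, 86.6% and 91.0%. All steps ran in R 4.3.3 with limma 3.58.1, and the figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Gene set collections, transcription factor binding data and clinical data were not used here.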

Results

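Gene expression was measured on 24 Affymetrix HG-U133 Plus 2.0 arrays, 12 from VCaP and 12 from LNCaP, both androgen-responsive human prostate cancer lines. VCaP carries a fusion of TMPRSS2 with ERG and LNCaP a rearranged ETV1, and both ERG and ETV1 are transcription factors of the ETS family. VCaP cells received small interfering RNA against ERG (siERG) or a control (siControl), and LNCaP cells a short hairpin RNA against ETV1 (shETV1) or a control (shControl). RNA interference lasted 24 h, then came 2 days without hormone and 16 h with ethanol (EtOH) or 10 nM dihydrotestosterone (DHT), a natural androgen. Each of the 8 groups held 3 arrays, described as biological replicates, and this number limits the precision of every value. All changes below are log2 units ± standard error with n = 3 arrays per group, and p-values are adjusted over the genes tested, 12840 in VCaP and 12823 in LNCaP. The data were read for what each knockdown changes with and without androgen, and whether both act on the androgen response in one direction.

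ERG fell in siERG cells by 0.82 ± 0.06 with EtOH (adjusted p = 1.83e-05) and by 1.09 ± 0.06 with DHT (adjusted p = 2.22e-06). Its mean intensity ± SD over 3 arrays was 1031 ± 82.3 in siControl and 576 ± 13.5 in siERG with EtOH, and 1188 ± 24.9 and 548 ± 17.5 with DHT. Over its 4 probe sets ERG was 44.1% to 57.6% lower, and each knockdown array lay below each control array. ETV1 fell in shETV1 cells by 0.61 ± 0.07 with EtOH (adjusted p = 4.91e-04) and by 0.62 ± 0.07 with DHT (adjusted p = 4.70e-04). Its intensity was 1149 ± 103 in shControl and 745 ± 28.5 in shETV1 with EtOH, and 1294 ± 31.0 and 835 ± 49.6 with DHT, and its 5 probe sets were 30.9% to 42.1% lower. In one fit of all 24 arrays, where scattered ETV1 values of VCaP enter the spread, the fall of ETV1 did not pass (adjusted p = 0.322 and 0.276). ETV1 did not pass in VCaP after siERG (0.80 ± 0.40 with EtOH, 0.72 ± 0.40 with DHT), and ERG was not tested in LNCaP, where group means were 7.45 to 10.6 for the probe set used and 49.2 to 58.6 for the brightest of 4. DHT raised ERG in siControl cells by 0.20 ± 0.06 (adjusted p = 0.0126, but 0.0510 in the fit of all 24 arrays and 0.0501 with the GAPDH ratio below as a covariate) and did not change ETV1 in shControl cells (0.17 ± 0.07, adjusted p = 0.0624).

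**Figure D1:**
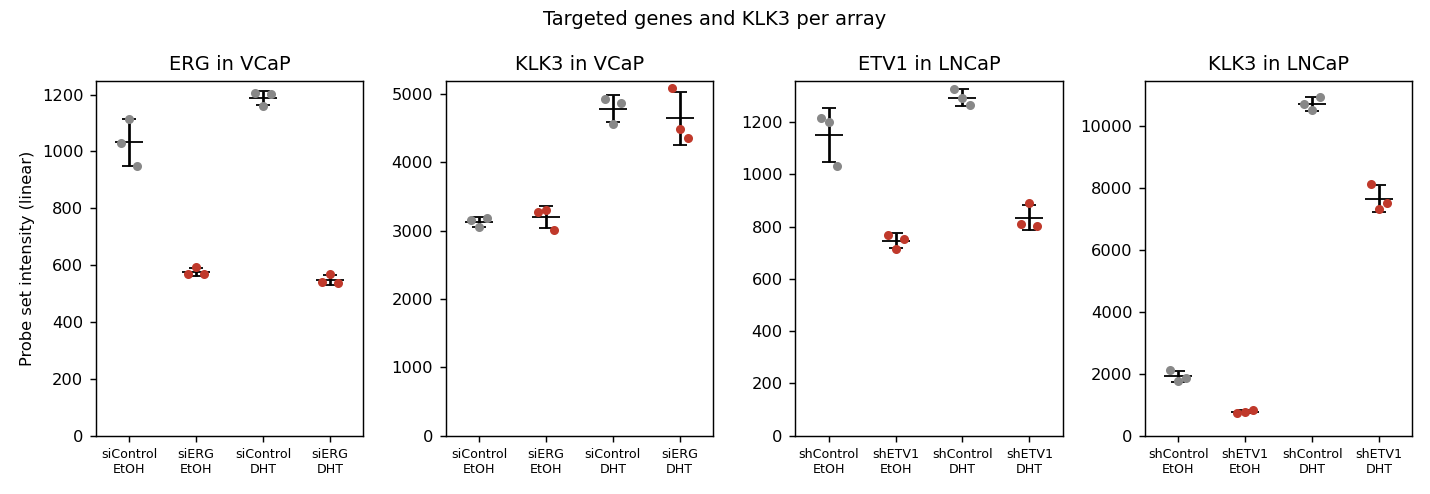
Intensity of ERG and KLK3 in VCaP and of ETV1 and KLK3 in LNCaP for each group. Points are the 3 arrays, bars are mean ± SD on a linear axis from 0, and ERG and ETV1 lie lower in each knockdown, as from 1031 to 576 for ERG with EtOH.

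In VCaP with EtOH, siERG lowered S100P, which encodes a calcium-binding protein, by 1.88 ± 0.11 (adjusted p = 5.80e-06) and SLPI, a protease inhibitor, by 1.57 ± 0.08 (adjusted p = 4.35e-06). EML6 fell by 1.99 ± 0.11 and INSM1 by 1.18 ± 0.08. SNAI2, a repressor of epithelial genes, rose by 0.95 ± 0.10 (adjusted p = 1.92e-04), and so did TNFRSF19 (0.90 ± 0.06, adjusted p = 1.23e-05). MYC, a driver of growth genes, fell by 0.94 ± 0.11 (adjusted p = 4.98e-04), TMPRSS2 rose by 0.32 ± 0.06 (adjusted p = 0.0101), and KLK3, the gene of prostate-specific antigen, did not change (0.03 ± 0.06). In all, 690 genes rose and 754 fell, 2 and 22 of them at least 2-fold, while 661 rose and 539 fell with averaged probe sets. The total of 1444 became 873, 900 and 950 without siControl EtOH replicates A, B and C, and 805 and 870 without siERG EtOH replicates B and C. The GAPDH 3' to 5' ratio, a sign of RNA quality, was 1.09 ± 0.02 in siERG and 1.05 ± 0.01 in siControl arrays (mean ± SD, exact p = 0.1, the smallest possible). With it as a covariate, chosen after seeing the data, 113 genes rose and 162 fell, and TMPRSS2 did not pass (0.39 ± 0.10, adjusted p = 0.0947). Standard errors grow with this covariate, here to a median of 1.54 times. With the ACTB ratio, chosen likewise, which was 3.05 and 3.31 (exact p = 0.6), 652 rose and 541 fell.

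Genes of cholesterol synthesis rose after siERG with EtOH, 11 of 18 tested members, or 13 adjusted over the list alone, with a median of 0.28 (camera, adjusted p = 1.75e-09; adjusted p = 0.362 with an estimated correlation). ACAT2 (0.53 ± 0.06) and MSMO1 (0.41 ± 0.05), both enzymes of that pathway, were among them, and the other 7 members did not pass. Of 21 genes of the unfolded protein response, 4 rose and 17 did not pass, 6 adjusted over the list alone (median 0.08, adjusted p = 0.0127; adjusted p = 0.489 with an estimated correlation). DNAJB9, a chaperone partner in the endoplasmic reticulum, rose by 0.32 ± 0.04. The list call was lost without siERG EtOH replicate B (adjusted p = 0.0617) and without _x_at and _s_at probe sets (0.0683). Among 30 androgen-induced genes 9 rose, STEAP4 fell (−0.65 ± 0.06, adjusted p = 1.04e-04) and 20 did not pass, 13 adjusted over the list alone (median 0.08, adjusted p = 0.0394; adjusted p = 0.489 with an estimated correlation). This call was lost without siControl EtOH replicate B (0.0583), siERG EtOH replicate B (0.0617) or siControl DHT replicate B (0.0533), without _x_at and _s_at probe sets (0.181) and in a fit of only these 2 groups (0.0664). Luminal epithelium genes fell in 4 of 12 members, 6 adjusted over the list alone (median −0.11, adjusted p = 0.0179; adjusted p = 0.489 with an estimated correlation). Among them were KRT18, a keratin (−0.55 ± 0.07), and SPDEF, an ETS factor of luminal cells (−0.52 ± 0.06). That call was lost without siControl EtOH replicate B (0.0583) and without _x_at and _s_at probe sets (0.359).

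The other 11 lists did not pass after siERG with EtOH. Some passed under other settings: basal epithelium without _x_at and _s_at probe sets (0.0167) or without siControl EtOH replicate C (0.0457), fatty acid synthesis without siControl EtOH replicate A (0.0446), interferon without that array (6.65e-03) or siERG EtOH replicate C (6.51e-03). Of 20 fatty acid genes 4 rose, ELOVL6 among them (0.48 ± 0.06), and 6 passed adjusted over the list alone (list adjusted p = 0.101). Of 32 cell cycle genes 5 fell, including MCM2, part of the replicative helicase (−0.42 ± 0.08), and 5 passed adjusted over the list alone (list adjusted p = 0.939). FAS, a death receptor gene induced by p53, fell by 0.45 ± 0.04 among 3 fallen of 17 p53 targets, 4 adjusted over the list alone (list adjusted p = 0.168). Of 25 androgen metabolism genes AKR1C1, whose probe set may bind related transcripts, fell by 0.68 ± 0.11 and HSD17B11 by 0.24 ± 0.04, while 1 rose and 6 passed adjusted over the list alone (list adjusted p = 0.581). Of 9 androgen-repressed genes BCHE, a cholinesterase, fell by 0.57 ± 0.09 and 1 rose, 4 adjusted over the list alone (list adjusted p = 0.939). In the invasion mesenchymal list 3 of 15 rose, SNAI2 among them, and 1 fell, 7 adjusted over the list alone (list adjusted p = 0.475). ETS family genes rose in 1 and fell in 3 of 20, 4 adjusted over the list alone (0.128), and basal epithelium genes fell in 2 of 4, also 2 adjusted over the list alone (0.128). INSM1 and DDC (−0.83 ± 0.06) fell among 13 neuroendocrine genes, 3 adjusted over the list alone (0.475). Of 8 tested markers of other cell types LUM rose (0.46 ± 0.10), LYZ and 1 more fell, and 3 passed adjusted over the list alone (0.475). No member of 23 interferon response genes passed, CXCL10 being nearest (0.35 ± 0.10, adjusted p = 0.0504, list adjusted p = 0.214). With the GAPDH ratio as a covariate ELOVL6, MCM2, AKR1C1, HSD17B11, BCHE and LUM did not pass (adjusted p from 0.0851 to 0.240), and the interferon (median −0.49, adjusted p = 1.50e-05) and ETS family lists (0.0408) passed downward.

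In VCaP with DHT, siERG lowered EML6 by 1.85 ± 0.11 (adjusted p = 3.36e-06), S100P by 1.68 ± 0.11 and SLPI by 1.37 ± 0.08. ST6GAL1 fell by 1.51 ± 0.05 (adjusted p = 1.62e-07). PGM2L1 (0.77 ± 0.09, adjusted p = 5.83e-04) and PDLIM1 (0.73 ± 0.11) rose, as did C5orf46 (1.03 ± 0.19). KLK3 (−0.04 ± 0.06), TMPRSS2 (0.03 ± 0.06) and MYC (0.07 ± 0.11) did not change. In all, 487 genes rose and 665 fell, 1 and 32 of them at least 2-fold, while array weights gave 1209 risen and 1004 fallen. The total of 1152 became 764 and 687 without siControl DHT replicates A and C, and 721 without siERG DHT replicate B. The 3' to 5' ratio of ACTB, a sign of RNA quality, was 2.84 ± 0.31 in siERG and 3.5 ± 0.06 in siControl arrays with DHT (mean ± SD, exact p = 0.1, the smallest possible). With this ratio as a covariate 659 genes changed, 364 up and 295 down. The GAPDH ratio was 1.03 ± 0.007 and 1.07 ± 0.008 (exact p = 0.1), and with it 60 genes rose and 212 fell, PGM2L1, PDLIM1 and C5orf46 not among them (adjusted p from 0.0617 to 0.211).

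With DHT, cholesterol synthesis genes rose after siERG in 7 of 18 members, 14 adjusted over the list alone (median 0.19, adjusted p = 2.84e-07; adjusted p = 0.601 with an estimated correlation). DHCR7, the last enzyme of the pathway, rose by 0.54 ± 0.06. The unfolded protein response rose in 4 of 21, 6 adjusted over the list alone (median 0.11, adjusted p = 2.11e-04; adjusted p = 0.601 with an estimated correlation). The other 13 lists did not pass. Under other settings 3 of them passed downward: interferon without the filter (0.0452), in a fit of only these groups (0.0144), in one fit of all arrays (0.0498) or without siERG DHT replicate B (0.0139), basal epithelium without _x_at and _s_at probe sets (0.0146) or the filter (2.54e-03), and luminal epithelium with averaged probe sets (0.0163) or without siControl DHT replicate B (0.0250). Of 30 androgen-induced genes 5 rose, such as MAF (0.55 ± 0.05), and 3 fell, such as STEAP4 (−0.42 ± 0.06), 10 adjusted over the list alone (list adjusted p = 0.308). Of 25 androgen metabolism genes AKR1C2 (−0.92 ± 0.10) and AKR1C1 (−0.97 ± 0.11), which share related sequence, fell together with 1 more, and 1 rose, 4 adjusted over the list alone (0.849). FAS fell by 0.54 ± 0.04 among 17 p53 targets, 3 fallen and 1 risen, 4 adjusted over the list alone (0.607). INSM1 (−1.21 ± 0.08) and DDC (−0.64 ± 0.06) fell among 13 neuroendocrine genes, 2 adjusted over the list alone (0.308). SNAI2 (0.65 ± 0.10) and ADAMTS1, a secreted protease (0.58 ± 0.08), rose in the invasion mesenchymal list, 3 risen and 2 fallen of 15, 6 adjusted over the list alone (0.741). STEAP4 (0.0856) and ADAMTS1 (0.109) did not pass with the GAPDH ratio as a covariate. With EtOH and with DHT 255 genes rose after siERG and 386 fell, against 26.2 and 39.1 if the 2 comparisons, which share no arrays, were independent across genes.

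DHT in VCaP siControl cells raised FKBP5, a chaperone partner of steroid receptors, by 1.90 ± 0.07 (adjusted p = 1.30e-08). TMPRSS2, an androgen-regulated protease, rose by 0.71 ± 0.06 (adjusted p = 7.63e-06) and KLK3 by 0.61 ± 0.06 (adjusted p = 2.19e-05). ORM1, an acute phase protein, rose by 3.64 ± 0.19. PPFIA2 fell by 2.91 ± 0.08 (adjusted p = 2.84e-09), and MYC by 2.30 ± 0.11 (adjusted p = 7.32e-08). WNT2, a secreted signal, fell by 2.47 ± 0.07 and BCHE by 2.40 ± 0.09. In all, 2517 genes rose and 3267 fell, 127 and 268 of them at least 2-fold. The majority turned with scaling, to 3157 risen and 2974 fallen after quantile normalization and 3192 and 2849 after centring of arrays. ACTB ratios were 3.5 with DHT and 3.31 with EtOH (exact p = 0.4), and GAPDH ratios 1.07 and 1.05 (exact p = 0.1).

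Of 30 androgen-induced genes 20 rose with DHT in VCaP siControl, 2 fell and 8 did not pass, 23 adjusted over the list alone (median 0.54, adjusted p = 1.08e-09; adjusted p = 0.0945 with an estimated correlation). STEAP4, a metalloreductase, rose by 1.72 ± 0.06 and PTGER4, a prostaglandin receptor, fell by 1.0 ± 0.05. Of 9 androgen-repressed genes 7 fell, OPRK1, an opioid receptor, by 1.79 ± 0.07, and UGT2B28, whose probe set may bind related transcripts, rose by 0.77 ± 0.18, with 9 adjusted over the list alone (median −1.23, adjusted p = 4.71e-05). Cholesterol synthesis rose in 13 of 18 and fell in 1, 15 adjusted over the list alone (median 0.45, adjusted p = 3.74e-06; adjusted p = 0.247 with an estimated correlation), NSDHL by 1.01 ± 0.07. Of 21 genes of the unfolded protein response 20 rose, 21 adjusted over the list alone, DNAJB9 by 1.15 ± 0.04 (median 0.64, adjusted p = 2.30e-12; adjusted p = 0.0945 with an estimated correlation). Cell cycle genes fell in 18 of 32, also 18 adjusted over the list alone, MCM2 by 0.98 ± 0.08 and MCM5 by 0.92 ± 0.08 (median −0.26, adjusted p = 2.45e-04; adjusted p = 0.426 with an estimated correlation). Fatty acid genes rose in 10 of 20 and fell in 2, 12 adjusted over the list alone, ACLY, which makes acetyl-CoA, by 0.65 ± 0.06 (median 0.18, adjusted p = 0.0139; adjusted p = 0.329 with an estimated correlation). The ETS family list passed with averaged probe sets (0.0461) and interferon without siControl EtOH replicate B (0.0235). In the reported fit the other 9 lists did not pass, though SPDEF (1.10 ± 0.06), SNAI2 (1.72 ± 0.10) and KRT19 (0.96 ± 0.08) rose and FAS (−1.07 ± 0.04), FN1 (−1.09 ± 0.07), HSD17B6 (−1.34 ± 0.10) and LUM (−0.68 ± 0.10) fell.

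In siERG cells DHT raised KLK3 by 0.54 ± 0.06 (adjusted p = 5.47e-05) and TMPRSS2 by 0.42 ± 0.06 (adjusted p = 3.34e-04), while ERG did not change (−0.07 ± 0.06, adjusted p = 0.350). BCHE (−2.21 ± 0.09), OPRK1 (−2.10 ± 0.07) and MYC (−1.29 ± 0.11) fell. Altogether 2575 genes rose and 3238 fell, but 3181 and 2979 after quantile normalization and 3068 and 2961 after centring. GAPDH ratios were 1.03 with DHT and 1.09 with EtOH (exact p = 0.1), and with this ratio as a covariate 915 rose and 1602 fell, at a median standard error 2.08 times as large. TMPRSS2 (0.32 ± 0.13, adjusted p = 0.131) and KLK3 (0.34 ± 0.12, 0.0718) were not among them. Of 30 androgen-induced genes 22 rose and 2 fell, 25 adjusted over the list alone (median 0.42, adjusted p = 5.43e-10; adjusted p = 0.0813 with an estimated correlation). Of 9 androgen-repressed genes 7 fell and 1 rose, 8 adjusted over the list alone (median −1.36, adjusted p = 1.06e-04). Cholesterol synthesis rose in 14 of 18 and fell in 1, 16 adjusted over the list alone, DHCR7 by 0.85 ± 0.06 (median 0.32, adjusted p = 2.62e-05; adjusted p = 0.321 with an estimated correlation). All 21 genes of the unfolded protein response rose (median 0.58, adjusted p = 3.51e-13; adjusted p = 0.0813 with an estimated correlation). Of 32 cell cycle genes 17 fell while 1 rose, 19 adjusted over the list alone (median −0.25, adjusted p = 3.57e-04; adjusted p = 0.450 with an estimated correlation). The other 10 lists did not pass, but luminal epithelium passed upward under 3 other settings or without siERG DHT replicate A (0.0296 to 0.0466), and the ETS family under 2 or without siERG EtOH replicate C or siERG DHT replicate A (0.0306 to 0.0434). Interferon passed upward with the GAPDH ratio (3.15e-04). Both in siControl and in siERG cells 1970 genes rose and 2560 fell with DHT, against 505 and 824 if independent, and 11 and 4 went opposite ways. Here too both calls of a gene used the same spread.

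The DHT response differed between siERG and siControl cells for 37 genes, 8 more positive and 29 more negative in siERG, with 1401 genes at an unadjusted p below 0.05. ERG itself (−0.27 ± 0.08), TMPRSS2 (−0.29 ± 0.09) and KLK3 (−0.07 ± 0.09) did not pass. The fall of MYC with DHT was smaller in siERG cells by 1.01 ± 0.16 (adjusted p = 0.0342), and SRM, a polyamine enzyme gene that MYC induces, differed by 0.51 ± 0.08 (adjusted p = 0.0342). TGFBR3 (0.64 ± 0.09), FZD10 (0.64 ± 0.10), and NEO1 (0.55 ± 0.07) were also more positive. BRDT (−1.37 ± 0.23), LINC00920 (−1.01 ± 0.17), ST3GAL1 (−0.97 ± 0.14), GPAT3 (−0.84 ± 0.11) and MAB21L3 (−0.76 ± 0.11) were more negative. Without the intensity filter none of these 10 genes passed (adjusted p from 0.0578 to 0.112). Each lost its call when any one of 5 to 10 of the 12 arrays was left out (adjusted p up to 0.126, for MYC up to 0.0973 with 9 such arrays). Of the 37 genes, 21.6% were more positive, against 36.2% after quantile normalization. The number was 6, 0 and 14 without siControl EtOH replicates A, B and C, and 9, 10 and 5 without siERG EtOH replicates A, B and C. It was 4, 14 and 12 without siControl DHT replicates A, B and C, and 15, 9 and 74 without siERG DHT replicates A, B and C. With the ACTB ratio as a covariate, chosen after seeing the data, 8 genes passed, MYC (0.0830) and SRM (0.0745) not among them. With replicate letters as a block (adjusted p from 0.0658 to 0.0958 for these 10) or with the GAPDH ratio as a covariate (0.572 to 0.84) 0 genes passed in limma. No list passed with camera, the nearest being cholesterol synthesis and fatty acid synthesis (adjusted p = 0.166), which passed without siERG EtOH replicate A (0.0473 each). With the GAPDH ratio as a covariate interferon genes passed upward (median 0.64, adjusted p = 2.42e-06), against a median of −0.04 without it.

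In LNCaP with EtOH, shETV1 lowered the androgen-induced kallikrein genes KLK2 by 1.90 ± 0.11 (adjusted p = 6.53e-06) and KLK3 by 1.29 ± 0.07 (adjusted p = 6.30e-06), and TMPRSS2 by 0.38 ± 0.05 (adjusted p = 2.61e-03). PCGEM1 fell by 1.13 ± 0.07 and RIPOR2 by 1.59 ± 0.08 (adjusted p = 2.43e-06). TNFRSF19 rose by 1.44 ± 0.06 (adjusted p = 1.85e-06) and BCHE by 1.32 ± 0.06 (adjusted p = 1.85e-06). In all, 157 genes rose and 381 fell, 3 and 10 of them at least 2-fold. The total of 538 became 280 without shControl EtOH replicate A, and 312, 317 and 327 without shETV1 EtOH replicates A, B and C. It was 142 with the GAPDH ratio as a covariate, and GAPDH ratios were 1.07 in shETV1 and 1.11 in shControl (exact p = 0.2), ACTB ratios 2.97 and 3.12 (exact p = 0.7).

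Androgen-induced genes fell after shETV1 with EtOH in 10 of 30 members and 20 did not pass, 18 adjusted over the list alone, KLK2 and KLK3 among them (median −0.17, adjusted p = 6.84e-10). Invasion mesenchymal genes fell in 4 of 10, 7 adjusted over the list alone, FN1, the gene of fibronectin, by 0.46 ± 0.04 (median −0.25, adjusted p = 9.06e-07). Basal epithelium genes fell in 2 of 4, also 2 adjusted over the list alone, ITGA6, an integrin, by 0.28 ± 0.05 (median −0.26, adjusted p = 2.87e-03; adjusted p = 0.0502 with an estimated correlation), though ITGA6 did not pass with the GAPDH ratio as a covariate (0.171). Among 17 p53 targets 2 rose, 4 adjusted over the list alone (median 0.13, adjusted p = 1.91e-03; adjusted p = 0.106 with an estimated correlation). No single gene of 32 in the cell cycle list passed in limma, PLK1, a mitotic kinase, being nearest (−0.38 ± 0.10, adjusted p = 0.0642). The list as a whole shifted down (median −0.08, adjusted p = 1.61e-03; adjusted p = 0.2 with an estimated correlation). Of 24 androgen metabolism genes 4 fell, STS, the steroid sulfatase, by 0.36 ± 0.05, 5 adjusted over the list alone (median −0.12, adjusted p = 0.0258; adjusted p = 0.139 with an estimated correlation). That call was lost without shControl EtOH replicate C or shETV1 EtOH replicate A (adjusted p up to 0.0888). It was also lost with averaged probe sets (0.0868), without _x_at and _s_at probe sets (0.420), with the stricter filter (0.119), in one fit of all arrays (0.1) and with the ACTB (0.0565) or GAPDH ratio (0.232) as a covariate. The unfolded protein response rose in 1 of 21, 4 adjusted over the list alone (median 0.05, adjusted p = 0.0422; adjusted p = 0.462 with an estimated correlation). It lost its call without shControl EtOH replicates A or C, shETV1 EtOH replicates B or C or shControl DHT replicate A (adjusted p up to 0.136), and under 8 other settings (adjusted p up to 0.397). Among the other lists ETS family genes passed downward without _x_at and _s_at probe sets (0.0348), without the filter (0.0187), with the stricter filter (0.0350), with the GAPDH ratio (0.0290) or without shControl EtOH replicate A (0.0414), and luminal genes with averaged probe sets (7.57e-03) or the GAPDH ratio (0.0349). In the reported fit the other 8 lists did not pass, with ACP3, the prostatic acid phosphatase, fallen by 0.60 ± 0.05 in the luminal list (2 of 11 fell, 3 adjusted over the list alone, list adjusted p = 0.132).

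In LNCaP with DHT, shETV1 raised BCHE by 1.65 ± 0.06 (adjusted p = 1.75e-07) and KLHL1 by 1.52 ± 0.05 (adjusted p = 6.54e-08), and lowered KLK3 by 0.49 ± 0.07 (adjusted p = 4.15e-03). KLK2 did not pass (−0.37 ± 0.11, adjusted p = 0.0910). TMPRSS2 fell by 0.22 ± 0.05 (adjusted p = 0.0444), a call lost with averaged probe sets (0.140), without the filter (0.110), in a fit of only these 2 groups (0.0890) and with the GAPDH ratio as a covariate (0.0563). It was also lost when any one of 9 arrays was left out, namely shControl EtOH replicate A, shETV1 EtOH replicates A, B and C, shControl DHT replicates A and B, and shETV1 DHT replicates A, B and C (adjusted p up to 0.139). SLITRK3 (1.32 ± 0.09) and SRGAP2 (0.99 ± 0.14) rose. RIPOR2 (−1.46 ± 0.08), GRIN3A (−1.36 ± 0.08) and RAI2 (−1.20 ± 0.07) fell. In all, 344 genes rose and 321 fell, 5 and 6 of them at least 2-fold. The rising share was 51.7%, against 37.8% after quantile normalization and 26.9% after centring of arrays. The total of 665 became 364 and 329 without shControl DHT replicates A and B, and 328 and 353 without shETV1 DHT replicates A and C. GAPDH ratios were 1.08 in shETV1 and 1.09 in shControl (exact p = 0.1), and with this ratio as a covariate 207 rose and 233 fell. ACTB ratios were 3.07 and 2.76 (exact p = 0.2), and with that ratio 269 rose and 184 fell.

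Androgen-induced genes fell after shETV1 with DHT in 3 of 30 and 27 did not pass, 6 adjusted over the list alone (median −0.11, adjusted p = 1.27e-05; adjusted p = 0.0707 with an estimated correlation). Androgen-repressed genes rose in 4 of 8, also 4 adjusted over the list alone, CAMK2N1, an inhibitor of a calcium-dependent kinase, by 0.72 ± 0.04 (median 0.27, adjusted p = 1.27e-05; adjusted p = 0.0531 with an estimated correlation). Luminal genes fell in 4 of 11, 6 adjusted over the list alone, ACP3 by 0.85 ± 0.05 and CD24 by 0.47 ± 0.07 (median −0.06, adjusted p = 2.38e-05; adjusted p = 0.0531 with an estimated correlation). ITGA6 fell by 0.39 ± 0.05, the only one of 4 basal genes to pass, also 1 adjusted over the list alone (median −0.24, adjusted p = 2.33e-03; adjusted p = 0.0531 with an estimated correlation). Invasion mesenchymal genes fell in 5 of 10, also 5 adjusted over the list alone (median −0.12, adjusted p = 3.44e-04; adjusted p = 0.0707 with an estimated correlation), a call lost without the filter (0.115). Cholesterol synthesis fell in 2 of 18, 3 adjusted over the list alone (median −0.02, adjusted p = 0.0289; adjusted p = 0.0707 with an estimated correlation). That call was lost without shControl DHT replicate A (0.0610), without _x_at and _s_at probe sets (0.491) and without the filter (0.0658). Of 17 p53 targets no single one passed in limma, PHLDA3 being nearest (0.42 ± 0.11), and 3 passed adjusted over the list alone. The list as a whole rose (median 0.11, adjusted p = 0.0205; adjusted p = 0.164 with an estimated correlation), but not without shControl DHT replicate A or shETV1 DHT replicate B (adjusted p up to 0.101). The other 8 lists did not pass, but fatty acid synthesis passed downward after centring (0.0345), with array weights (0.0492) or without shControl DHT replicate C (0.0381) or shETV1 DHT replicate C (0.0127). With EtOH and with DHT 84 genes rose after shETV1 and 181 fell, against 4.21 and 9.54 if independent.

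**Figure D2:**
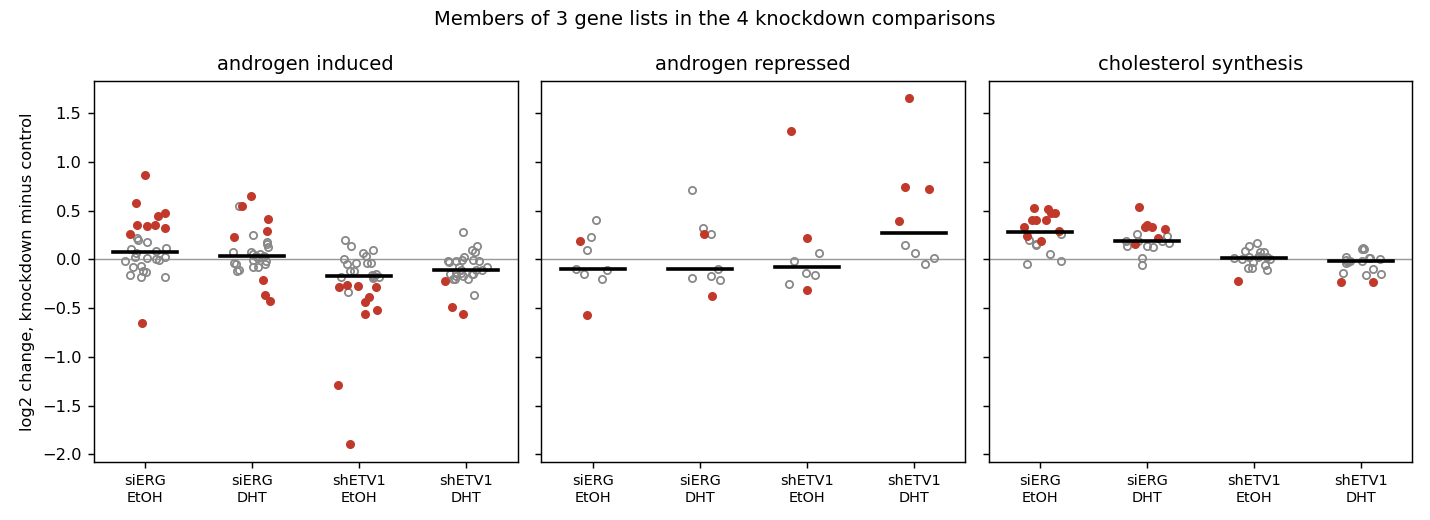
Members of the androgen-induced, androgen-repressed and cholesterol synthesis lists in the 4 knockdown comparisons, as log2 change. Filled red points passed the test, open grey points did not, and black lines are medians, 0.28 for cholesterol synthesis after siERG with EtOH and −0.17 for androgen-induced genes after shETV1 with EtOH.

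DHT in LNCaP shControl cells raised KLK2 by 4.26 ± 0.11 (adjusted p = 3.44e-10), TMPRSS2 by 3.04 ± 0.05 (adjusted p = 3.22e-11), KLK3 by 2.47 ± 0.07 (adjusted p = 7.66e-10) and FKBP5 by 3.52 ± 0.07. ORM1 rose by 5.33 ± 0.11, STEAP4 by 5.17 ± 0.08 and SNAI2 by 4.11 ± 0.10. OPRK1 fell by 4.0 ± 0.08 (adjusted p = 5.40e-11), and so did AMIGO2 (−3.48 ± 0.16). MYC did not change (0.07 ± 0.08, adjusted p = 0.526). In all, 2382 genes rose and 2855 fell, 260 and 204 of them at least 2-fold, against 2723 risen and 2605 fallen after centring of arrays. ACTB ratios were 2.76 with DHT and 3.12 with EtOH (exact p = 0.2), and GAPDH ratios 1.09 and 1.11 (exact p = 0.4).

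Of 30 androgen-induced genes 28 rose with DHT in LNCaP shControl and TSC22D3 fell (−0.20 ± 0.05), 30 adjusted over the list alone, NDRG1, a differentiation gene, rising by 2.99 ± 0.04 (median 2.08, adjusted p = 1.19e-28). All 8 tested androgen-repressed genes fell (median −1.76, adjusted p = 9.27e-09). Cholesterol synthesis rose in 13 of 18 and fell in 1, 14 adjusted over the list alone, HMGCS1 by 1.11 ± 0.05 (median 0.47, adjusted p = 3.85e-06). The unfolded protein response rose in 11 of 21 and fell in 3, 16 adjusted over the list alone, EDEM1 by 0.95 ± 0.04 (median 0.36, adjusted p = 2.61e-03; adjusted p = 0.242 with an estimated correlation). Fatty acid genes rose in 7 of 18 and fell in 2, 9 adjusted over the list alone, FASN, the fatty acid synthase, by 1.08 ± 0.06 (median 0.06, adjusted p = 0.0425; adjusted p = 0.242 with an estimated correlation). That call was lost without shETV1 EtOH replicate B or shControl DHT replicate C (adjusted p up to 0.0550) and under 7 other settings (adjusted p up to 0.119). Interferon response genes fell in 12 of 21 and rose in 2, 15 adjusted over the list alone (median −0.25, adjusted p = 0.0425; adjusted p = 0.116 with an estimated correlation). IFIH1 fell by 0.69 ± 0.08 and HERC5 rose by 0.79 ± 0.05. The list lost its call without shControl EtOH replicate C or shControl DHT replicates A or C (adjusted p up to 0.0943) and under 7 other settings (adjusted p up to 0.379). Other lists passed under some settings: invasion mesenchymal without _x_at and _s_at probe sets (median 1.32, adjusted p = 4.68e-03), p53 targets downward with averaged probe sets (0.0410) or without the filter (0.0343), luminal epithelium without the filter (0.0430) and non epithelial markers downward with the stricter filter (0.0351). In the reported fit the other 9 lists did not pass, with SPDEF (2.12 ± 0.06), KRT19 (2.34 ± 0.04) and TWIST1 (1.32 ± 0.08) risen and UGT2B15 (−1.88 ± 0.06) and UGT2B17 (−1.56 ± 0.06), androgen-clearing enzymes with related sequence, fallen.

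In shETV1 cells DHT raised KLK2 by 5.79 ± 0.11, KLK3 by 3.28 ± 0.07 (adjusted p = 1.19e-10) and TMPRSS2 by 3.20 ± 0.05 (adjusted p = 2.76e-11), and ETV1 did not pass (0.16 ± 0.07, adjusted p = 0.0881). OPRK1 (−3.47 ± 0.08) and ACKR3 (−1.94 ± 0.05) fell. Altogether 2417 genes rose and 2439 fell, a near balance that turned under 11 other settings, as to 2196 and 1960 with averaged probe sets. Androgen-induced genes rose in 28 of 30 and fell in 1, 29 adjusted over the list alone (median 2.16, adjusted p = 8.14e-30), and all 8 androgen-repressed genes fell (median −1.43, adjusted p = 1.09e-08). Cholesterol synthesis rose in 13 of 18 and fell in 2, 16 adjusted over the list alone, SQLE by 0.77 ± 0.04 (median 0.43, adjusted p = 5.36e-05). The unfolded protein response rose in 12 of 21 and fell in 5, 18 adjusted over the list alone (median 0.30, adjusted p = 0.0282; adjusted p = 0.412 with an estimated correlation), a call at 0.0502 after quantile normalization. The other 11 lists did not pass. The p53 targets passed downward under 5 other settings or without shControl EtOH replicate A, shETV1 EtOH replicate B or shETV1 DHT replicate B (0.0188 to 0.0493). Interferon did so under 3 or without shControl EtOH replicate A or shETV1 DHT replicate C (0.0259 to 0.0462). Invasion mesenchymal (0.0104), fatty acid synthesis (0.0351) and non epithelial markers (0.0462) passed under 1 setting each. In both kinds of LNCaP cells 1957 genes rose and 2071 fell with DHT, against 449 and 543 if independent.

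The DHT response differed between shETV1 and shControl cells for 13 genes, 10 more positive and 3 more negative in shETV1, with 962 genes at an unadjusted p below 0.05. ETV1 (−0.01 ± 0.10) and TMPRSS2 (0.17 ± 0.08) did not pass. KLK2 rose more with DHT in shETV1 cells by 1.53 ± 0.16 (adjusted p = 8.12e-03) and KLK3 by 0.80 ± 0.10 (adjusted p = 0.0199), from the lower levels that both had with EtOH. CAMK2N1 (0.66 ± 0.05, adjusted p = 1.02e-03), CTBP1-AS (0.75 ± 0.08) and KLHL1 (0.57 ± 0.06) were also more positive. ANGPT2 (−1.40 ± 0.18), TNFRSF19 (−0.59 ± 0.09) and ACAD8 (−0.46 ± 0.05) were more negative. With averaged probe sets the calls of KLK2 (0.42 ± 0.07, adjusted p = 0.0691), KLK3 (0.0674), KLHL1 (0.922) and TNFRSF19 (0.986) were lost. In one fit of all arrays that of KLHL1 was lost (0.983), and without the filter those of KLK3, ANGPT2, TNFRSF19 and ACAD8 (0.0571 to 0.134). The total was 8 and 7 without shControl EtOH replicates A and B, and 8, 7 and 8 without shETV1 EtOH replicates A, B and C. It was 8, 8 and 7 without shControl DHT replicates A, B and C, and 8 without shETV1 DHT replicate A. With the ACTB ratio as a covariate, or with replicate letters as a block, 1 gene passed, CAMK2N1. With the GAPDH ratio as a covariate 4 passed, KLHL1, ANGPT2, TNFRSF19 and ACAD8 not among them (0.0567 to 0.0727). KLK3 lost its call without shETV1 EtOH replicates A or B, shControl DHT replicates A, B or C or shETV1 DHT replicate A (adjusted p up to 0.0806). ANGPT2 lost it without shControl EtOH replicates B or C, shControl DHT replicates A or C or shETV1 DHT replicate A (up to 0.0686), and TNFRSF19 when any one of 11 arrays was left out (up to 0.132).

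Of 8 androgen-repressed genes CAMK2N1 and ACKR3 (0.52 ± 0.08) were more positive in the DHT response of shETV1 cells, 6 adjusted over the list alone (median 0.33, adjusted p = 1.66e-10), that is, their fall with DHT was smaller. Androgen-induced genes were more positive in 2 of 30, KLK2 and KLK3, 7 adjusted over the list alone (median 0.08, adjusted p = 3.98e-03; adjusted p = 0.320 with an estimated correlation), a call lost without _x_at and _s_at probe sets (0.0984) and with the ACTB (0.108) or GAPDH ratio (0.0861) as a covariate. ACKR3 lost its call with averaged probe sets (0.725), with replicate letters as a block (0.0923), with the GAPDH ratio (0.12) and when any one of 10 of the 12 arrays was left out (adjusted p up to 0.126). Luminal genes were more negative (median −0.12, adjusted p = 1.84e-04; adjusted p = 0.0737 with an estimated correlation; 0.0533 without _x_at and _s_at probe sets), with no gene passing downward and 2 of 11 adjusted over the list alone. The unfolded protein response was more negative (median −0.07, adjusted p = 1.20e-03; adjusted p = 0.320 with an estimated correlation), with no gene passing downward. Cell cycle genes were more positive (median 0.08, adjusted p = 3.98e-03; adjusted p = 0.320 with an estimated correlation), but not without shETV1 DHT replicate C (0.0539). Cholesterol synthesis, with no gene passing downward, was more negative (median −0.04, adjusted p = 0.0105; adjusted p = 0.0737 with an estimated correlation), but not without shControl EtOH replicate B (0.0778), without _x_at and _s_at probe sets (0.496) or after quantile normalization (0.0501). Invasion mesenchymal genes passed upward without the filter (0.0336) and with the ACTB (0.0208) or GAPDH ratio (0.0433) as a covariate, and the remaining lists did not pass.

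The effects of lowering ETV1 in LNCaP and ERG in VCaP differed for 1176 of 12305 genes with EtOH and 923 with DHT. Factor, line, reagent, knockdown depth and probably processing differ together and cannot be separated. With the GAPDH ratio as a covariate 288 differed with EtOH, and with the ACTB ratio 594 with DHT. With EtOH the ETV1 effect minus the ERG effect was −1.41 ± 0.42 for ETV1 (adjusted p = 0.0424), −1.31 ± 0.10 for KLK3, −0.71 ± 0.08 for TMPRSS2 and −1.77 ± 0.13 for KLK2. The ETV1 value lost its call without the filter (adjusted p = 0.0764), with the GAPDH ratio (0.491) and when any one of 16 of the 24 arrays was left out (up to 0.101). It combines the fall of ETV1 in LNCaP with its higher value after siERG in VCaP, which did not pass by itself. S100P (2.30 ± 0.13), BCHE (1.88 ± 0.11), EML6 (1.5 ± 0.15) and SLPI (1.46 ± 0.16) lay higher in LNCaP, RIPOR2 (−2.16 ± 0.19), BRDT (−1.83 ± 0.20) and PCGEM1 (−1.71 ± 0.11) lower. With DHT the difference was −0.44 ± 0.10 for KLK3 (adjusted p = 7.76e-03), and it did not pass for ETV1 (−1.34 ± 0.42, adjusted p = 0.0622) or TMPRSS2 (−0.25 ± 0.08, adjusted p = 0.0783). Androgen-induced genes lay lower in LNCaP with EtOH, 16 of 30 against 1 higher, 25 adjusted over the list alone (median −0.35, adjusted p = 5.10e-13). With DHT it was 7 against 1, 12 adjusted over the list alone (median −0.16, adjusted p = 1.67e-06). Cholesterol synthesis lay lower with EtOH in 10 of 18, also 10 adjusted over the list alone, MSMO1 by 0.63 ± 0.06 (median −0.25, adjusted p = 2.31e-08). With DHT it lay lower in 8, 11 adjusted over the list alone (median −0.24, adjusted p = 1.47e-09). Invasion mesenchymal genes lay lower with EtOH, FN1 by 0.75 ± 0.07 and SNAI2 by 1.12 ± 0.15, 7 adjusted over the list alone (median −0.46, adjusted p = 2.53e-06). Androgen-repressed genes lay higher with DHT in 4 of 8, 5 adjusted over the list alone (median 0.41, adjusted p = 8.24e-05).

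Of the remaining lists that differed between the knockdowns with EtOH, p53 targets lay higher in LNCaP in 3 of 17, also 3 adjusted over the list alone, FAS by 0.56 ± 0.09 (median 0.14, adjusted p = 7.61e-03; adjusted p = 0.124 with an estimated correlation). That call was lost with averaged probe sets (0.1) and without _x_at and _s_at probe sets (0.441). Fatty acid genes lay lower in 4 of 18, 5 adjusted over the list alone (median −0.13, adjusted p = 0.0408; adjusted p = 0.432 with an estimated correlation). ELOVL6 lay lower in LNCaP (−0.63 ± 0.10), and the list lost its call without siControl EtOH replicate C, siERG EtOH replicate B, shControl EtOH replicates A or B or shETV1 EtOH replicate A and under 4 other settings (adjusted p up to 0.118). With DHT the unfolded protein response lay lower in 3 of 21, 7 adjusted over the list alone (median −0.16, adjusted p = 8.43e-05; adjusted p = 0.267 with an estimated correlation). Invasion mesenchymal genes lay lower with DHT in 3 of 10, also 3 adjusted over the list alone, ADAMTS1 among them (−0.61 ± 0.09; list median −0.26, adjusted p = 2.26e-04), but not without _x_at and _s_at probe sets (0.0704) or without the filter (0.228). Luminal genes lay lower with DHT in 2 of 11, 3 adjusted over the list alone, ACP3 among them (−0.75 ± 0.06; list median −0.09, adjusted p = 0.0192; adjusted p = 0.322 with an estimated correlation). This was lost without siControl DHT replicate B (0.0877), without _x_at and _s_at probe sets (0.0682) and with the GAPDH ratio as a covariate (0.0646). Interferon genes, which did not pass, lay higher in LNCaP with DHT under 5 other settings (adjusted p from 0.0178 to 0.0455), and without siControl EtOH replicates A or B, siERG EtOH replicate C, siControl DHT replicate B, siERG DHT replicate B or shControl DHT replicate B (4.10e-03 to 0.0446). With EtOH they did so with the GAPDH ratio (2.28e-04) or without siControl EtOH replicate A (0.0198) or siERG EtOH replicate C (0.0155). Cell cycle genes lay lower with EtOH without siControl EtOH replicate A (0.0369), and p53 targets higher with DHT with averaged probe sets (0.0238), without the filter (0.0352) or without shControl DHT replicate B (0.0430).

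With EtOH 20 genes rose after both, TNFRSF19, GCG and MIPEP among them, and 56 fell, such as EML6, PLA1A, REG4, RAI2 and KLF4, against 7.94 and 20.2 if independent across genes, and the comparisons share no arrays. RIPOR2, BRDT and PCGEM1 were among 51 genes that rose after siERG and fell after shETV1 (19.6 if independent), S100P and BCHE among 12 with the opposite pattern (8.20 if independent). With DHT 25 rose after both, 59 fell, 38 rose after siERG and fell after shETV1 and 22 did the reverse, against 12.5, 14.3, 11.5 and 15.5. Across 12305 genes, which are not independent, the 2 effects had a correlation of 0.02 ± 0.03 with EtOH and 0.04 ± 0.02 with DHT.

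Genes that DHT induced by at least 1 log2 unit in LNCaP shControl shifted up after siERG in VCaP with EtOH, where 59 of 253 rose and 29 fell (median 0.08, adjusted p = 5.86e-03; adjusted p = 0.533 with an estimated correlation). With DHT 43 rose and 29 fell, and the shift did not pass (adjusted p = 0.184). Genes repressed in LNCaP shControl shifted down after siERG with DHT, 32 of 196 fallen and 13 risen (median −0.04, adjusted p = 5.86e-03; adjusted p = 0.455 with an estimated correlation). With EtOH 28 fell and 15 rose, and the shift did not pass (adjusted p = 0.137). These 4 shifts kept their direction with the GAPDH ratio as a covariate. The 2 that had passed no longer did, at medians of 0.08 (adjusted p = 0.0815) and −0.04 (0.0814), and the other 2 passed at 0.03 (0.0229) and −0.02 (0.0178). Genes induced in VCaP siControl shifted down after shETV1 in LNCaP with DHT, 22 of 115 fallen and 3 risen (median −0.12, adjusted p = 3.76e-10). Genes repressed there shifted up, 39 of 203 risen and 10 fallen (median 0.10, adjusted p = 1.51e-03; adjusted p = 0.279 with an estimated correlation). With EtOH neither list shifted after shETV1 (adjusted p = 0.184 and 0.132), though the repressed one passed without siControl EtOH replicate B (0.0332), siControl DHT replicates A, B or C (0.0355, 0.0437 and 0.0350) or shControl EtOH replicate A (0.0429).

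DHT acted on KLK2 (3.90 ± 0.13), KLK3 (1.87 ± 0.10) and TMPRSS2 (2.32 ± 0.08) more strongly in LNCaP shControl than in VCaP siControl. PTGER4 (3.79 ± 0.12), IRS2, an adaptor of insulin signals (3.47 ± 0.14), and STEAP4 (3.45 ± 0.10) lay higher in LNCaP. CSMD1 (−2.66 ± 0.25), IRX3 (−2.52 ± 0.07) and OPRK1 (−2.21 ± 0.11) lay lower. In all, 3929 of 12305 genes differed, 2164 higher in LNCaP and 1765 lower, but 1994 and 2333 after quantile normalization and 1997 and 2188 after centring. Of 30 androgen-induced genes 27 lay higher in LNCaP, 29 adjusted over the list alone (median 1.43, adjusted p = 3.80e-30). Androgen-repressed genes lay lower in 5 and higher in 2 of 8, 7 adjusted over the list alone (median −0.62, adjusted p = 0.01; 0.113 without _x_at and _s_at probe sets). The difference was −1.69 ± 0.07 for ACKR3 and 1.67 ± 0.17 for FOLH1. Cell cycle genes lay higher in 13 and lower in 1, 16 adjusted over the list alone, MCM5 by 0.95 ± 0.11 (median 0.20, adjusted p = 0.0134; adjusted p = 0.790 with an estimated correlation). This call was lost without siControl DHT replicate A (0.0664) and without _x_at and _s_at probe sets (0.0720). The unfolded protein response lay lower in 9 and higher in 2, 13 adjusted over the list alone (median −0.16, adjusted p = 4.41e-03; adjusted p = 0.790 with an estimated correlation; 0.0720 without _x_at and _s_at probe sets). Interferon genes passed, lower in LNCaP, under 3 other settings (0.0353 to 0.0429) or without siControl EtOH replicate B, siERG EtOH replicate C, siControl DHT replicate B, siERG DHT replicate B or shControl EtOH replicate B (2.89e-03 to 0.0479). In both lines 1217 genes rose with DHT and 1422 fell, against 464 and 686 if independent. Another 194 rose in VCaP and fell in LNCaP, such as IRX3, RIN2 and ST3GAL1, and 241 fell in VCaP and rose in LNCaP, such as PTGER4, IRS2 and ST6GALNAC1, against 554 and 575. Across genes the DHT responses had a correlation of 0.482 ± 0.0151.

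**Figure D3:**
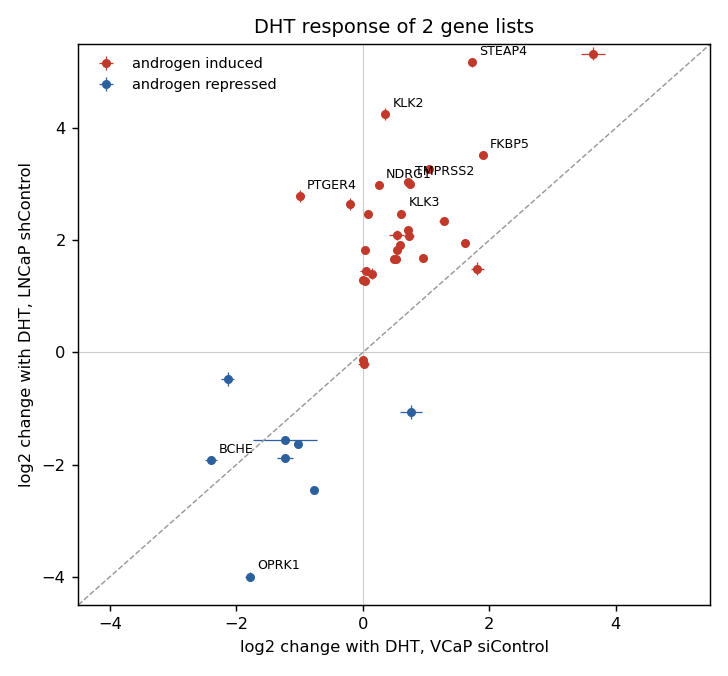
DHT response of androgen-induced (red) and androgen-repressed (blue) genes in VCaP siControl (horizontal) and LNCaP shControl (vertical), as log2 change with standard errors. The dashed line marks equal responses, and most androgen-induced genes lie above it (27 of 30 higher in LNCaP).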

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

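Each result here stood out because a test of the difference between the effects in 2 groups passed, either siERG or shETV1 cells against their controls or LNCaP against VCaP. For each count below 14 of the 100 drawn splits kept the real labels in one of the 2 effects compared, and with them its real changes, so the next highest count is no level without change. The 85 splits that kept neither gave at most 2, 1, 2, 8 and 1 genes, in the order below. But they remove both effects, move them into the spread of the fit and do not test their difference by itself. Among the explanations weighed below, the test of the targets of MYC was chosen only after the result was seen, and the fits with the ACTB or GAPDH ratio only after the data were seen.

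DHT lowered MYC less in siERG than in siControl cells of VCaP, by 1.01, and the difference may follow from the lower level that MYC already had in siERG cells with EtOH (−0.94 ± 0.11). One array alone could decide this value: without each array in turn it lay between 0.87 and 1.14, with an adjusted p up to 0.0973, under the limit of 0.2 set beforehand, which is lenient since 9 of the 12 values lay above 0.05. Other probe sets could not be asked, because MYC has 1. If the level of MYC protein follows, targets of MYC should move with it: the median interaction of 20 tested targets was 0.215, 19 of them positive and 0 passing singly in limma (the list does not hold SRM, which passed), with a camera p of 6.51e-09, or 0.0124 with an estimated correlation. The design holds no group that separates a direct action of ERG on MYC from a floor in its fall, so no biological explanation was tested. The call of MYC was also lost with replicate letters as a block (adjusted p = 0.0857) and with the ACTB ratio as a covariate (0.97 ± 0.17, 0.0830). With the GAPDH ratio it was 0.86 ± 0.32 (0.834), where the value changed by less than its standard error and that error doubled from 0.16.

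The other 9 named interaction values in VCaP were 0.64 for TGFBR3, 0.64 for FZD10, 0.55 for NEO1, 0.51 for SRM, −1.37 for BRDT, −1.01 for LINC00920, −0.97 for ST3GAL1, −0.84 for GPAT3 and −0.76 for MAB21L3, and the interaction held 37 genes in all. In 100 drawn splits of the arrays the real labels gave the highest count, a share of 1%, with 23 genes in the next. With replicate letters as a block, or with the GAPDH ratio as a covariate, 0 genes passed in limma.

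The LNCaP interaction held 13 genes, against 7 in the next of 100 drawn splits (1%). Values were 1.53 for KLK2, 0.80 for KLK3, 0.75 for CTBP1-AS, 0.66 for CAMK2N1, 0.57 for KLHL1, −1.40 for ANGPT2, −0.59 for TNFRSF19 and −0.46 for ACAD8. List medians were 0.0756 for androgen induced, 0.326 for androgen repressed, −0.0446 for cholesterol synthesis, 0.0795 for cell cycle, −0.0666 for unfolded protein response and −0.125 for luminal epithelium. With an estimated correlation the androgen-repressed list passed, and the others did not (adjusted p = 0.320, 0.0737, 0.320, 0.320 and 0.0737 in the order given).

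With EtOH 1176 genes differed between the effects of shETV1 in LNCaP and siERG in VCaP, against 536 in the next of 100 drawn splits (1%). Gene values were 2.30 for S100P, 1.88 for BCHE, 1.5 for EML6, 1.46 for SLPI, 1.28 for SLITRK3, −2.16 for RIPOR2, −1.83 for WDR72, −1.83 for BRDT, −1.77 for KLK2 and −1.71 for PCGEM1. List medians were −0.348 for androgen induced, −0.250 for cholesterol synthesis, −0.131 for fatty acid synthesis, 0.140 for p53 targets and −0.464 for invasion mesenchymal. With an estimated correlation fatty acid synthesis (adjusted p = 0.432) and p53 targets (0.124) did not pass.

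With DHT 923 genes differed between the 2 knockdowns, against 466 in the next of 100 drawn splits (1%). Gene values were 2.03 for BCHE, 1.88 for S100P, 1.64 for EML6, 1.63 for HLA-DMB, 1.46 for ST6GAL1, −1.64 for GRIN3A, −1.51 for C5orf46, −1.41 for COL12A1, −1.33 for CRISPLD1 and −1.27 for PCGEM1. List medians were −0.159 for androgen induced, 0.414 for androgen repressed, −0.242 for cholesterol synthesis, −0.164 for unfolded protein response, −0.259 for invasion mesenchymal and −0.0896 for luminal epithelium. With an estimated correlation the unfolded protein response (adjusted p = 0.267) and luminal epithelium (0.322) did not pass.

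The DHT response differed between the control cells of the 2 lines for 3929 genes, against 3694 in the next of 100 drawn splits (1%). Gene values were 3.90 for KLK2, 3.79 for PTGER4, 3.55 for LINC00844, 3.47 for IRS2, 3.45 for STEAP4, −2.66 for CSMD1, −2.59 for TMEM140, −2.52 for IRX3, −2.21 for GPR63 and −2.21 for OPRK1. List medians were 1.43 for androgen induced, −0.624 for androgen repressed, 0.198 for cell cycle and −0.162 for unfolded protein response. With an estimated correlation the last 2 did not pass (adjusted p = 0.790 each).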

How the results depend on the processing

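Pseudocount 32 and centring of arrays left all 13 gene counts within 1.5 times, and the 4 DHT counts moved further under the 1 log2 unit limit and, in siERG cells, with the GAPDH ratio as a covariate. The array signal limits genes near background: without the intensity filter the counts of shETV1 fell to 275 with EtOH, 332 with DHT and 5 in the interaction, and the VCaP interaction fell to 8, where more genes tested mean a stricter adjustment. For the other values below the cause was not tested, except that stricter limits give fewer genes by construction.

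Averaged probe sets gave 357 genes for shETV1 with EtOH, 17 in the VCaP and 7 in the LNCaP interaction. Without _x_at and _s_at probe sets the interactions held 19 and 4 genes. The filter at the 60th percentile gave 20 in LNCaP, quantile normalization 58 in VCaP, the trended and robust variance 39 in LNCaP, pseudocount 1 gave 24 in VCaP. Array weights gave 2235 and 2213 for siERG with EtOH and DHT, 157 and 22 in the VCaP and LNCaP interactions, and 1858 and 1501 differences between the knockdowns with EtOH and DHT.

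Changes of at least 1 log2 unit numbered 24 and 33 for siERG with EtOH and DHT, 395 and 377 for DHT in siControl and siERG, 3 in the VCaP interaction, 13 and 11 for shETV1, 464 and 407 for DHT in shControl and shETV1, 2 in the LNCaP interaction, and 48, 46 and 381 for the line differences of knockdown with EtOH, knockdown with DHT and the DHT response. An adjusted p below 0.01 left 610 and 528 for siERG, 5 in the VCaP interaction, 211 and 222 for shETV1, 6 in the LNCaP interaction, and 541 and 488 differences between knockdowns.

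A fit of only the groups compared gave 527 for siERG with DHT, 281 for shETV1 with EtOH and 269 with DHT. One fit of all 24 arrays gave 96 in the VCaP and 28 in the LNCaP interaction. With the ACTB ratio as a covariate, chosen after seeing the data, siERG with DHT gave 659, the interactions 8 and 1, and the difference between knockdowns with DHT 594. The GAPDH ratio as a covariate, also chosen after seeing the data, separates several groups. With it siERG gave 275 with EtOH and 272 with DHT, DHT in siERG cells 2517, shETV1 142 and 440, the interactions 0 and 4, and the difference between knockdowns with EtOH 288. Its median standard error was 1.05 to 2.08 times that of the reported fit. Genes that lost their call kept a median of 0.835 to 1.0 of their change and all kept its direction, except with DHT in siERG cells, where 3346 of 3450 did. Shifts after siERG kept their direction but no longer passed for genes DHT-induced in LNCaP with EtOH (0.0786) and DHT-repressed with DHT (−0.0411), and passed for DHT-repressed with EtOH (−0.0245) and DHT-induced with DHT (0.0344). The interferon list turned upward in the VCaP interaction (0.644, adjusted p = 2.42e-06).

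Replicate letters taken as a block gave 0 genes in the VCaP interaction, 1 in the LNCaP interaction and 429 for shETV1 with DHT. The letters do not pair the samples: after removal of group means, arrays with the same letter had correlations of −0.117 to 0.112 in VCaP and −0.218 to 0.125 in LNCaP, and 2 and 1 of 18 pairs exceeded 0.1.

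The androgen-induced list after siERG with EtOH lost its call without _x_at and _s_at probe sets (0.107, adjusted p = 0.181), in a fit of only these groups (0.0775, 0.0664) and with an estimated correlation (0.0775, 0.489). After shETV1 with DHT the androgen-induced (−0.108) and androgen-repressed (0.268) lists lost theirs with an estimated correlation (adjusted p = 0.0707 and 0.0531). Among the shifts, averaged probe sets brought the genes DHT-repressed in VCaP past the threshold after shETV1 with EtOH (−0.0429), and exclusion of _x_at and _s_at probe sets did so for genes DHT-repressed in LNCaP after siERG with EtOH (−0.0212). An estimated correlation ended 3 shift calls (0.0765, −0.0392 and 0.103, with adjusted p = 0.533, 0.455 and 0.279). The correlation across genes of the 2 knockdowns with EtOH was −0.0127 by Spearman, that with DHT was 0.0102 without the filter, and that of the DHT responses was 0.439, 0.396 and 0.4999 by Spearman, without the filter and with the stricter filter.

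Values that turned direction were, with averaged probe sets, GDF15 after siERG with EtOH (0.0581) and in the line difference (−0.0554), MVK with DHT in siERG cells (0.19), DDC after shETV1 with EtOH (−0.04) and ASNS with DHT in shControl cells (0.0766). Without _x_at and _s_at probe sets these were IDI1 with DHT in siControl (−0.37) and shControl cells (−0.27), and IDI1 (0.13) and ELK4 (−0.0758) in the line difference with EtOH.

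Without each array in turn, counts ran from 805 to 1961 and 687 to 1578 for siERG with EtOH and DHT, 5065 to 6261 and 4958 to 5961 for DHT in siControl and siERG, 0 to 74 in the VCaP interaction, 280 to 522 and 328 to 629 for shETV1, 4660 to 5258 and 4103 to 4936 for DHT in shControl and shETV1, 7 to 12 in the LNCaP interaction, and 867 to 1454, 710 to 1156 and 3562 to 4234 for the line differences. The highest VCaP counts came without siERG DHT replicate C. Androgen-induced medians ran from 0.065 to 0.094 and 0.012 to 0.079 after siERG, and from −0.197 to −0.150 and −0.127 to −0.098 after shETV1. Androgen-repressed medians ran from −0.128 to 0.045 and −0.139 to −0.040 after siERG, and from −0.158 to −0.032 and 0.225 to 0.352 after shETV1. The shift of genes DHT-repressed in VCaP after shETV1 with EtOH ran from −0.0389 to −0.00783. Correlations ran from 0.005 to 0.035, 0.027 to 0.047 and 0.471 to 0.482.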

Other observations

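SNAI2, which represses epithelial genes, rose with DHT by 1.72 ± 0.10 in VCaP siControl and by 4.11 ± 0.10 in LNCaP shControl, and it rose after siERG by 0.95 ± 0.10 with EtOH. TNFRSF19 rose with DHT in VCaP siControl by 1.84 ± 0.06 and after both knockdowns with EtOH (0.90 ± 0.06 for siERG, 1.44 ± 0.06 for shETV1). BCHE fell with DHT in VCaP siControl by 2.40 ± 0.09, fell after siERG with EtOH by 0.57 ± 0.09 and rose after shETV1 by 1.32 ± 0.06 with EtOH and 1.65 ± 0.06 with DHT. S100P and EML6 fell after siERG by 1.88 ± 0.11 and 1.99 ± 0.11 with EtOH.

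The tests of a general loss of the DHT response and of the GAPDH ratio below were chosen only after the data were seen. The following are hypotheses.

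Hypothesis: lowering ERG may raise cholesterol synthesis genes in VCaP (median 0.278 with EtOH, 18 members). Array scaling stays undecided, since 2 scalings moved the median of all genes only from 0.0075 to 0.0053 and 0.0106. Their lower list median was 0.281 (adjusted p = 9.51e-11 after quantile normalization and 1.09e-09 after centring). These p-values use the preset correlation, and the unscaled list did not pass (adjusted p = 0.362 with an estimated correlation). RNA quality would pull the median towards 0, but with the GAPDH 3' to 5' ratio, which separates these groups, as a covariate the median was 0.236 (adjusted p = 4.79e-09 with the preset correlation). The ACTB ratio did not separate them (exact p = 0.6), so the 0.302 with that ratio decides nothing. A general shift towards the DHT response, which also raises these genes, stays open. Subtraction of the part predicted from the DHT response of LNCaP shControl left 0.266, but with a slope of 0.0287 it could remove too little to decide. A repeat with other RNA interference sequences could tell whether the rise needs ERG, and no other biological explanation was tested.

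Hypothesis: lowering ETV1 may lower androgen-induced genes of LNCaP with or without DHT (median −0.108 with DHT and −0.173 with EtOH). With DHT the list did not pass (adjusted p = 0.0707 with an estimated correlation), and the p-values that follow use the preset one. The higher of 2 scalings left −0.111 (adjusted p = 6.64e-05 and 1.22e-05), which decides nothing (median of all genes 0.0204, then 0.0041 and −0.0209). The highest adjusted p without 1 array was 8.20e-05. Whether a general loss of the DHT response lies behind it stays open, since the values go both ways. Against it, the median of the list in the interaction was 0.0756 (0.0317 to 0.107 without single arrays), a call lost without _x_at and _s_at probe sets (0.0984), with either covariate and with an estimated correlation (adjusted p = 0.320). KLK2 and KLK3 rose more with DHT in shETV1 by 1.53 and 0.80, but by 0.42 and 0.53 with averaged probe sets, where neither passed (0.0691 and 0.0674). Nor did they pass with replicate letters as a block (0.0597 and 0.0732). With it go the smaller fall of androgen-repressed genes (interaction median 0.326, adjusted p below 0.05 also when the correlation was estimated) and the genes that DHT induced in VCaP, with a median of −0.117 after shETV1 with DHT and −0.00376 with EtOH. Genes repressed in VCaP had 0.103 and −0.0198, and these differences between DHT and EtOH were not tested. Across genes, which are not independent, the effect of shETV1 with DHT had a correlation of −0.119 with the DHT response of VCaP siControl (−0.126 to −0.107 without single arrays). A time course of KLK2 and BCHE after shETV1 at several DHT doses could test it, and no other biological explanation was tested.

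For the comparisons of 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. The real labels gave 1444, 1152, 5784 and 5813 genes in VCaP (siERG with EtOH, siERG with DHT, DHT in siControl, DHT in siERG), where the highest other splits gave 0, 14, 0 and 1. In LNCaP they gave 538, 665, 5237 and 4856 in the same order for shETV1, where the highest other splits gave 2, 1, 1 and 1. In each case 1 split, the real one, reached the real count, as in the drawn splits above.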
